A study of Mus musculus with 3 samples.

How the data were processed

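Single-cell RNA sequencing had been done on dissociated whole pituitaries of TpitWT, TpitHT and TpitKO mice, 1 library per genotype and 3 libraries in all. Tpit is the transcription factor encoded by Tbx19, and the genotypes are written WT, HT and KO here. The labels do not spell out HT, do not say how the allele was made and do not give the number of mice per library. Per the labels, cells were sorted with propidium iodide to leave out dead cells, loaded on Chromium 3′ v3 reagents with the aim of recovering 10000 cells per library, and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name Cell Ranger 5, Seurat 3.1, DESeq2 with no version, and the build names mm10 and GRCm38, without saying which step used which.

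The authors deposited a table of raw counts per gene, summed over the cells of each genotype and cluster, for 55403 gene rows and 61 combinations of genotype and cluster. The unit counts was checked on the values, which were whole numbers. The file headers do not say whether reads were collapsed to molecules. In cluster 0 the median gene of low expression had 1.26, 1.32 and 1.31 times as many counts per positive cell in WT, HT and KO as chance placement of single molecules would give. Reads left uncollapsed and differences between cells both raise this value and were not told apart, so the values are called counts. If reads were not collapsed, the intervals were too narrow for molecules. A further deposited table held the same sums multiplied by 1 factor per genotype and cluster. Its unit was recorded as signal, the authors' scaled counts, and it was used as an alternative only. The deposited tables also held quantities recorded under the unit other: the number of cells of each genotype and cluster with a count of each gene, and a table giving each cell barcode its genotype and its cluster number from 0 to 20. No counts per single cell were used. The planned steps that need them were therefore not run: medians of counts per cell, thinning of cells to equal depth, a doublet score, reassignment of cells by marker scores, and the share of cells with several G2M genes. Doublets were not treated beyond what the authors had done, means of counts per cell replaced medians, and proliferation was measured as the share of cells with an Mki67 count.

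Rows with the same gene symbol were added, which moved 110 rows and left 55293 symbols. Gene coordinates were those of the deposited table. They were identical to GENCODE M21 on GRCm38 for 52854 of the 53292 symbols found in both. The files name no cell types, so the 21 clusters were named by marker lists fixed in advance, as lactotrope-like (clusters 0 and 4), somatotrope-like (1, 2 and 5), gonadotrope-like (3), corticotrope-like (6), melanotrope-like (7), macrophage-like (8 and 19), endothelial-like (9), stem-cell-like (10), thyrotrope-like (14), fibroblast-like (15), pituicyte-like (18) and cycling (20). Clusters 11, 12, 13, 16 and 17 met no marker list alone and kept their numbers.

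The libraries held 11222 cells and 107289047 counts in WT, 12839 cells and 152382545 counts in HT, and 13413 cells and 133252735 counts in KO. With 1 library per genotype there was no spread between animals to compare with, so no test was run, no p-value was computed and no gene was called changed. No paired analysis was possible because each genotype had a single library. Counts were given exact Poisson intervals, shares of cells exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals, all at 95%. They cover counting error only and not the variation between cells, animals, dissections or libraries. Intervals of CPM and of ratios of CPM treat each count as independent, although counts come clustered in cells, so they are too narrow. A value of 0 was given the limit that 3 counts would allow. KO against WT was the main contrast, with KO against HT and HT against WT beside it. HT was not treated as a replicate of WT.

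Counts were summed per class and genotype and expressed relative to the total of the class as CPM. Log2 ratios were computed after adding 10 CPM to both values, and folds were plain ratios of CPM. A class was compared where both genotypes had at least 100 cells, which left 6 classes and the sum over all cells. The genes named in the text followed a rule: at least 50 counts in WT and KO together, at least 20 CPM in WT or KO, a log2 ratio of at least 1 in size against WT and of at least 0.5 in the same direction against HT. Up to 10 higher and 10 lower genes were named for all cells, the stem-cell-like class and the lactotrope-like class, up to 4 each way for other classes, and up to 5 each way for HT against WT by size alone. Mitochondrial, ribosomal, hemoglobin, sex-linked, and predicted genes were left out of the ranking, as were, within a class, the marker genes of that class. Tbx19, Pomc, the hormone genes and the leading members of each list described were named beside them.

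The 24 gene lists were POMC lineage, Pit1 lineage, gonadotrope, pituitary stem cell, cell cycle S, cell cycle G2M, cell cycle inhibitors, YAP/TAZ targets, Wnt targets, Notch pathway, BMP and TGF-beta, glucocorticoid-induced, immediate early and heat shock, unfolded protein response, secretory granule, epithelial junction, extracellular matrix, angiogenesis, growth factor and receptor, interferon response, sex-linked, hemoglobin, mitochondrial and ribosomal protein. Each list's median log2 ratio over members with at least 50 counts was placed as a percentile among the medians of 10000 random lists of the same size matched on expression in 20 bins. This describes these libraries and is not a test. Cdkn1a and Gadd45g stand in both the glucocorticoid-induced and the inhibitors lists. The samples, lists, markers, naming rule and a first set of alternatives were fixed before the data were examined. Chosen afterwards were the counting interval of list medians (1000 Poisson redraws), the rule that a list was described where its percentile was below 1 or above 99 on the same side against both WT and HT, the removal of hormone-cell profiles from class sums, and 7 added alternatives.

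Alternatives tried were TMM (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0) in R 4.3.3, totals without hormone and mitochondrial genes, and a pseudocount of 1 CPM. Shares were recomputed without macrophage-, endothelial-, fibroblast- and pituicyte-like cells and cluster 16. Other alternatives were at least 20 counts or no filter on counts, and at least 30 cells per class. Those chosen after the data were seen were shares outside clusters 6 and 7, cluster 12 counted as lactotrope-like, the authors' scaled counts, totals without nuclear copies of mitochondrial sequence, single clusters of a class, shares of cells with a Tbx19 count, and Top2a or the summed G2M list in place of Mki67. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

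The procedure was tested on simulated data. In a simulated stem-cell-like class of 6986 genes the naming rule recovered 23% of 100 genes planted at a 2-fold and 88% of 100 planted at a 4-fold difference, and passed 0 of 6786 genes left alike. In simulated sums over all cells of 5126 genes it recovered 1% and 96%, and passed 0 of 4926 genes left alike. The simulated libraries shared 1 expression profile and differed by Poisson error and the planted changes only. They held no other differences between libraries, no free RNA and no clustering of counts in cells. The 0 genes passed thus do not measure errors from those sources. Genes that differ 2-fold were mostly not named, since a log2 ratio of 1 was asked for after adding 10 CPM.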

Results

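Gene expression was measured in single cells of mouse pituitaries of 3 genotypes at the Tpit locus, WT, HT and KO, with 1 library each. The WT library held 11222 cells with a mean of 9561 counts per cell, the HT library 12839 cells with 11869, and the KO library 13413 cells with 9935. Totals were 107289047, 152382545 and 133252735 counts. A single library stands behind each genotype, so every interval given covers counting error only and no difference was tested against variation between animals. Intervals of CPM and of folds also leave out variation between cells, so narrow ones overstate how well a level is known. Mitochondrial genes took 1.64%, 1.59% and 1.74% of counts. The Y-linked gene Ddx3y was read at 68.3, 63.4 and 71.9 CPM, against 14, 19 and 18 counts in all of Xist, the transcript of the inactive X chromosome. The growth hormone gene Gh took 24.4%, 21.4% and 16.2% of all counts, and the prolactin gene Prl took 8.22%, 8.02% and 12.6%. Hemoglobin genes summed to 18.4 CPM in WT, 177 in HT and 152 in KO.

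The first comparison asked whether the libraries carried the genotypes their labels name. Tbx19, which encodes Tpit (ENSMUSG00000026572, chromosome 1, 165137855 to 165160773, minus strand, GRCm38, protein coding), was read at 17.6 CPM (16.8 to 18.4) in WT, 12.4 CPM (11.8 to 12.9) in HT and 0.690 CPM (0.557 to 0.847) in KO. WT over KO was 25.5 (20.6 to 31.7). Pomc, the gene of the precursor of ACTH and alpha-MSH (ENSMUSG00000020660, chromosome 12, 3954951 to 3960642, plus strand) and a known target of Tpit, stood at 21846 CPM in WT, 22576 in HT and 58.3 in KO, a WT over KO ratio of 375 (367 to 383). Tbx19 was counted in 8.78% of WT cells, 7.51% of HT cells and 0.522% of KO cells. Most of it lay in the corticotrope-like cluster 6, at 142 CPM in WT and 99.3 in HT, and in the melanotrope-like cluster 7, at 106 and 97.6 CPM. Of the 92 Tbx19 counts of the KO library, 86 lay in cluster 11, where Tbx19 was at 13.6 CPM against 61.1 in WT and 76.2 in HT. The labels do not say which part of the gene was altered, so reads from its 3′ end do not by themselves check the label. A row that the authors named LacZp was at 0 counts in WT, which allows up to 0.0280 CPM, at 175 counts in HT and at 87 counts in KO. In HT it lay in cluster 6 with 92 counts, cluster 7 with 74 and cluster 11 with 7, and in KO cluster 11 held 83 of its counts, in 65 of 871 cells. Pomc counts were found in 96.8%, 98.7% and 24.1% of all cells, and in 92.3%, 98.2% and 3.80% of endothelial-like cells, which should not express the gene. Those endothelial-like cells had means of 3609.7, 4343 and 4249.6 counts per cell, below the means of all cells. Their Pomc was at 3212, 1295 and 10.7 CPM, and values at or below these were read as levels that free RNA could give. The same free RNA takes a smaller share of counts in cells with more counts. In such classes a CPM below these levels does not by itself show free RNA.

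**Figure D1:**
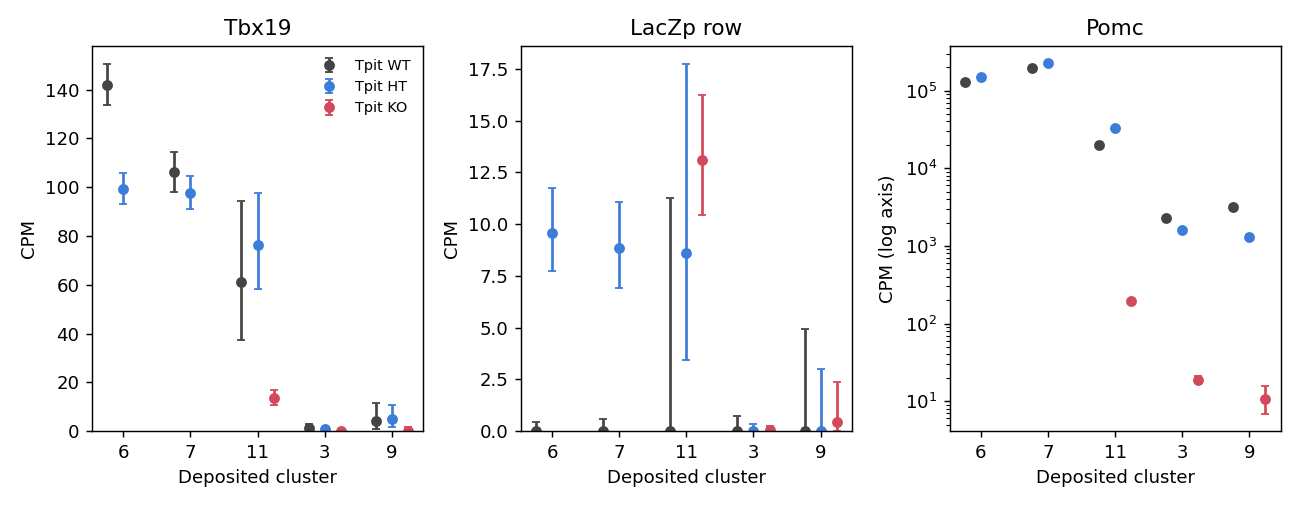
CPM of Tbx19, of the LacZp row and of Pomc in deposited clusters 6, 7, 11, 3 and 9 of the WT, HT and KO libraries (1 library each), with 95% Poisson intervals. Over all cells, which are not drawn, Tbx19 was at 17.6, 12.4 and 0.690 CPM, LacZp at 0, 1.15 and 0.653 CPM, and Pomc at 21846, 22576 and 58.3 CPM.

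The next comparison asked which cell types the pituitaries held, since the series concerns how pituitary lineages act on one another. Gonadotrope-like cells, which make luteinizing and follicle-stimulating hormone, were 4.001% of cells in WT (3.65 to 4.38), 4.91% in HT (4.54 to 5.29) and 12.4% in KO (11.84 to 12.96). Their share was 3.097-fold higher in KO than in WT (2.79 to 3.44) and 2.53-fold higher than in HT (2.30 to 2.77). Endothelial-like cells were 1.84%, 2.19% and 4.12% of cells, 2.23-fold higher in KO than in WT (1.898 to 2.63). Corticotrope-like cells, the source of ACTH, were 9.63% of WT and 8.08% of HT cells, melanotrope-like cells were 6.51% and 5.70%, and neither class held any of the 13413 KO cells, which allows a share of up to 0.0224%. Pomc was among the leading genes of both clusters, so their absence from KO was not measured independently of that transcript. The somatotrope-like share was 33.4% in WT, 29.8% in HT and 27.3% in KO, a KO over WT ratio of 0.818 (0.782 to 0.857). The lactotrope-like share was 34.9%, 39.0% and 34.4%, with a ratio of 0.988 (0.946 to 1.03). Because the KO library lacked clusters 6 and 7, all other shares of KO cells stood higher in part by arithmetic. Among cells outside those clusters the KO over WT ratio was 2.60 (2.34 to 2.89) for gonadotrope-like, 1.87 (1.59 to 2.21) for endothelial-like, 0.828 for lactotrope-like and 0.686 for somatotrope-like cells. On that base the ratio of macrophage-like cells moved from 1.16 (1.01 to 1.34) to 0.977 (0.847 to 1.13). That of stem-cell-like cells moved from 1.32 (1.12 to 1.54) to 1.10 (0.943 to 1.29). Both intervals then included equal shares, so whether these classes differed depended on the base chosen and was not settled. Setting those clusters aside took 1811 cells from WT and none from KO. Higher KO shares of some classes, such as gonadotrope-like cells, also lower all other KO shares by arithmetic. On either base, a lower lactotrope-like or somatotrope-like ratio thus does not by itself show a loss of those cells. Fibroblast-like cells were 0.508%, 0.771% and 1.07% of cells. Thyrotrope-like cells, which make thyroid-stimulating hormone, were 0.811%, 0.405% and 1.17%, with 91, 52 and 157 cells.

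**Figure D2:**
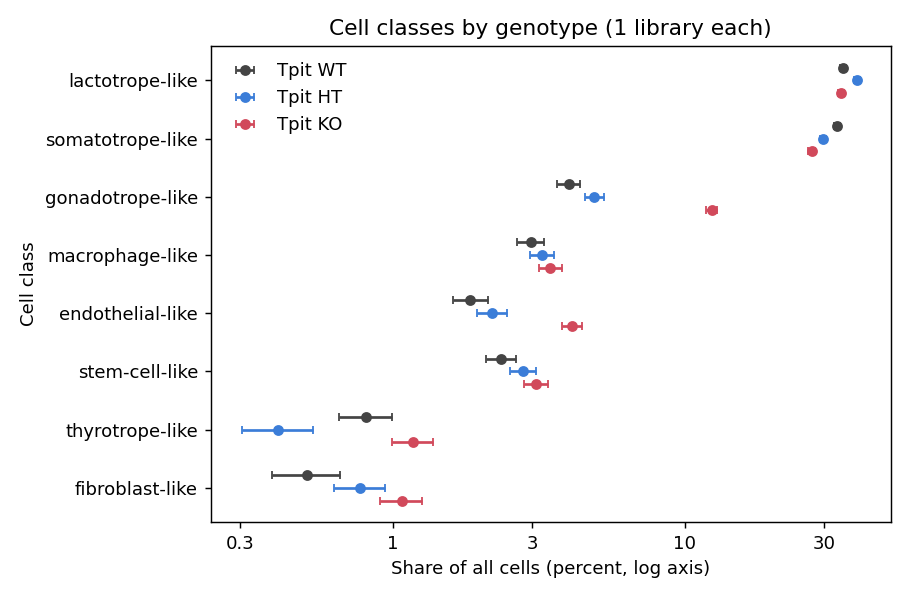
Share of cells in percent for lactotrope-, somatotrope-, gonadotrope-, macrophage-, endothelial-, stem-cell-, thyrotrope- and fibroblast-like cells in the WT, HT and KO libraries (1 library each), with 95% Clopper-Pearson intervals. Gonadotrope-like cells were at 4.001%, 4.91% and 12.4%. The corticotrope-like and melanotrope-like classes, which are not drawn, held none of the 13413 KO cells.

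Within classes the clusters were distributed unevenly. The somatotrope-like cells of WT and HT lay in clusters 1 (1635 and 1715 cells) and 2 (2081 and 2092 cells), whereas those of KO lay in clusters 1 (1188 cells) and 5 (2457 cells). Cluster 2 held 17 KO cells, and cluster 5 held 28 WT and 24 HT cells. Among lactotrope-like cells, cluster 4, led by Prl, was 2.07-fold higher in KO than in WT (1.88 to 2.28), and cluster 0, led by the neuropeptide gene Gal, had a ratio of 0.795 (0.757 to 0.835). Cluster 11 held 53 cells in WT, 107 in HT and 871 in KO, and the pituicyte-like cluster 18, of the glia of the neural lobe, held 9, 2 and 107. Clusters 5, 11 and 18 were drawn mostly from the KO library, and with 1 library per genotype a feature of that library and a kind of cell cannot be told apart.

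Over all cells, the genes that stood higher in KO were led by those of gonadotropes. Cga, the common subunit of the glycoprotein hormones (ENSMUSG00000028298, chromosome 4, 34893779 to 34907370), was at 7765 CPM in WT, 12225 in HT and 31157 in KO, 4.01-fold higher in KO than in WT (4.003 to 4.022). Gnrhr, the receptor of gonadotropin-releasing hormone (chromosome 5, 86180754 to 86197901), was at 75.3, 106 and 324 CPM, 4.31-fold higher (4.20 to 4.41). Tgfbr3l was 3.09-fold and Spp1, which encodes osteopontin, 4.21-fold higher. Rgs4, a regulator of G protein signalling, was 5.42-fold higher (5.12 to 5.74). Lhb, the beta subunit of luteinizing hormone, stood 2.97-fold higher (2.94 to 2.99), as did AC151602.1, whose near-identical values come from an overlapping row, but with the authors' scaled counts the log2 ratios of both were -0.012. The endothelial fatty acid carrier Fabp4 was at 13.3, 22.8 and 56.4 CPM, Aebp1 at 7.59, 11.8 and 39.5 CPM, and Cldn10, a leading gene of the pituicyte-like cluster, at 6.01, 4.26 and 39.9 CPM. On the lower side, after Pomc, came Oacyl, a marker of melanotropes, at 26.2, 37.9 and 1.28 CPM, 20.6-fold lower in KO than in WT (17.6 to 24.1). Esm1, Spink8 and Pappa2, a protease that frees IGF from its binding proteins, were 7.84-fold, 6.03-fold and 4.47-fold lower. Srxn1, an antioxidant enzyme, was 3.84-fold, Sparcl1 3.82-fold, Dapl1 3.80-fold and Gal 2.79-fold lower. Several of these genes mark clusters with few or no KO cells or with smaller KO shares: Oacyl and Esm1 were leading genes of cluster 7, Srxn1 of cluster 6, Pappa2 and Dapl1 of cluster 2, and Gal and Spink8 of cluster 0.

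The fixed lists were compared over all cells, where class shares enter every value. All 11 measured genes of the gonadotrope list were higher in KO than in WT, with a median log2 ratio of 1.07, against -0.012 with the authors' scaled counts, which weight each cluster by its own factor. Of the POMC lineage list, 10 of 12 genes were lower (median -0.60), with Avpr1b, the pituitary vasopressin receptor, at 8.49, 4.65 and 0.0225 CPM. The extracellular matrix list was higher in 15 of 15 genes (median 0.33), including Sparc at 34.9, 46.2 and 88.6 CPM and the basement membrane collagen Col4a1 at 3.06-fold. Of the angiogenesis list, 12 of 14 were higher (median 0.26), with Esm1 as the largest exception, including Vegfa at 10.2, 12.01 and 30.8 CPM and the fenestrated endothelium gene Plvap at 20.0, 29.1 and 44.9 CPM, beside an endothelial-like share 2.23-fold higher. The interferon response list was higher in 12 of 12 genes (median 0.24), with the membrane protein gene Bst2 at 14.2, 17.4 and 37.6 CPM. The immediate early and heat shock list had a median of 0.20 (12 of 14 higher), the pituitary stem cell list 0.18 (15 of 17 higher, Ednrb at 4.49, 6.26 and 12.3 CPM), and the epithelial junction list 0.15 (13 of 15 higher, Cldn7 at 16.3, 20.0 and 30.7 CPM). With the authors' scaled counts the angiogenesis median was 0.11, and these last 3 were 0.11, 0.067 and 0.016. The glucocorticoid-induced list was the other one that stood lower, at -0.43 (-0.45 to -0.40), in 13 of 16 genes. The other lists did not lie outside the random lists on the same side against both WT and HT, or measure library quality. Their medians were 0.01 for Pit1 lineage, 0.01 for cell cycle S, -0.06 for cell cycle G2M, -0.04 for cell cycle inhibitors, 0.08 for YAP/TAZ targets, 0.04 for Wnt targets, 0.08 for the Notch pathway, 0.13 for BMP and TGF-beta, -0.08 for the unfolded protein response, 0.06 for secretory granule, 0.05 for growth factor and receptor, 0.08 for sex-linked, 0.92 for hemoglobin, 0.05 for mitochondrial and 0.13 for ribosomal protein genes.

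Lactotrope-like cells were the class with most cells (3913 in WT and 4619 in KO). Over the class Prl (chromosome 13, 27057570 to 27065205) was at 215984 CPM in WT, 194874 in HT and 302856 in KO, and the Prl-led cluster 4 took more of the KO class. Within cluster 4 Prl was at 517571, 495686 and 496403 CPM, and within cluster 0 at 138554, 141432 and 170066 CPM. Eno3, an enolase, was the gene named as higher, at 33.6, 39.0 and 95.9 CPM, 2.86-fold (2.68 to 3.04). Gal, the galanin gene, was at 569, 454 and 189 CPM, 3.01-fold lower in KO than in WT (2.94 to 3.09). The imprinted gene Nnat was at 9698, 8905 and 3469.6 CPM, although it also stood at 2044 CPM in WT and 459 CPM in KO endothelial-like cells. Spink8 was 6.94-fold lower (6.46 to 7.46), the adhesion molecule gene Alcam 4.63-fold (4.16 to 5.17), Dapl1 4.17-fold (3.80 to 4.57) and A2m 3.01-fold. Ntrk2, the receptor of BDNF, was at 179, 169 and 65.6 CPM, the retinol carrier Rbp4 at 192, 181 and 82.5 CPM, and B2m, the light chain of MHC class I, at 138, 110.3 and 52.5 CPM. Pomc was at 1186, 736 and 107 CPM, 11.1-fold lower (10.8 to 11.4). In WT and HT that was below its level in endothelial-like cells (3212 and 1295 CPM), but in KO it was above it (10.7 CPM), with a Pomc count in 46.4% of KO lactotrope-like cells (44.9 to 47.8) at a mean of 10736 counts per cell. Of the gonadotrope list, 9 of 11 genes were higher with a small median of 0.04 (0.19 with a pseudocount of 1 CPM), led by Cga at 836, 856 and 1579 CPM, below its levels in endothelial-like cells (1931, 1777 and 3507 CPM). Of the immediate early and heat shock list, 8 of 14 were higher (median 0.06, and 0.054 to 0.22 under the alternatives run), with Hspa1a at 118, 221 and 237 CPM. The 4 measured hemoglobin genes were higher in KO (median 1.21), genes that red cells make.

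Somatotrope-like cells, which make growth hormone, differed between the libraries in many genes, with clusters 1 and 2 standing for WT and HT and clusters 1 and 5 for KO. Gh (chromosome 11, 106300271 to 106301865) was at 572142 CPM in WT, 573248 in HT and 499756 in KO, and within cluster 1, which all libraries shared, at 680373, 684320 and 626615 CPM. Igf1 (chromosome 10, 87858265 to 87937042), the growth factor that Gh induces in many tissues, was at 1.76, 5.97 and 22.6 CPM, 12.8-fold higher in KO than in WT (10.2 to 16.4). These values were below its endothelial-like levels (4.02, 27.9 and 109 CPM), and free RNA was not told apart from expression. The calcium binding protein gene Calb1 was at 8.47, 12.8 and 62.8 CPM, 7.41-fold higher (6.65 to 8.29), and the kinase anchor gene Sphkap 4.48-fold higher (4.17 to 4.81). Hspa1a, a heat shock protein, was at 13.02, 38.2 and 68.3 CPM. Ceacam10, a leading gene of cluster 1, was at 32.1 and 22.1 CPM in WT and HT and had 4 counts in KO, a WT over KO ratio of 333 (129.95 to 1226). Alcam was 9.15-fold lower in KO (8.25 to 10.2), Srxn1 5.30-fold (4.96 to 5.66) and Pomc, whose 593, 494 and 12.6 CPM were near or below the level of endothelial-like cells, 47.0-fold (43.1 to 51.3). The immediate early and heat shock list was higher in 10 of 14 genes, with Hspa1b at 5.26, 17.6 and 28.8 CPM and Dnajb1 at 71.2, 85.0 and 143 CPM. Its median of 0.38, against 0.19 for matched random lists, was 0.099 to 0.39 under the alternatives run. The unfolded protein response list was lower in 14 of 16 genes (median -0.19, and -0.41 without hormone and mitochondrial genes in the totals), with Creld2 at 38.5, 27.6 and 22.8 CPM. It stood as low in HT, with medians of -0.21 HT over WT and -0.0031 KO over HT, where 8 of 16 were lower. All 10 measured genes of the gonadotrope list were higher (median 0.28), Cga and Pitx1, a transcription factor of pituitary lineages, with log2 ratios of 1.13 and 0.73, although Cga, at 634, 633 and 1403 CPM, was below its level in endothelial-like cells. Of the pituitary stem cell list, 5 of 9 were lower, with the keratin genes Krt8 and Krt18 at -0.99 and -0.60. Its median of -0.07 became 0.0037 with no filter on counts.

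Gonadotrope-like cells numbered 449 in WT, 630 in HT and 1662 in KO. Their Cga was at 131177, 166169 and 173212 CPM, Lhb at 12715, 14751 and 11247 CPM, and Fshb, the beta subunit of follicle-stimulating hormone, at 7521, 10102 and 4176 CPM. Rrad, a small GTPase gene, was 3.54-fold higher in KO than in WT (3.02 to 4.18), the cold-inducible gene Rbm3 3.13-fold (2.71 to 3.64), the diacylglycerol kinase gene Dgkk 2.97-fold (2.52 to 3.52) and Rgs4 2.28-fold (2.12 to 2.46). Serpina3c was at 95.8, 62.1 and 12.9 CPM, 7.45-fold lower (6.41 to 8.67), the epoxide hydrolase gene Ephx2 7.14-fold lower (6.003 to 8.51) and the apolipoprotein gene Apoc3 4.33-fold lower (3.995 to 4.69). Pomc was at 2315, 1621 and 18.9 CPM, below its level in endothelial-like cells in WT (3212 CPM) and above it in HT (1295 CPM) and KO (10.7 CPM). Gonadotrope-like cells had a mean of 11207 counts per cell in WT against 3609.7 in endothelial-like cells. The lower WT CPM therefore does not by itself show free RNA. All 16 genes of the unfolded protein response list were lower in KO (median -0.52, -0.56 to -0.48). Among them were the chaperone gene Hspa5 at 1589, 1310.1 and 1071 CPM, Sdf2l1 at 455, 319 and 213 CPM, and Creld2 and Manf, with log2 ratios of -0.96 and -0.65. The list stood lower in HT as well, with an HT over WT median of -0.28. The secretory granule list was higher in 11 of 15 genes (median 0.20), with Syt1 at 0.68, Ptprn at 0.54 and, on the other side, Rab3a at -0.58.

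In macrophage-like cells (334 in WT, 465 in KO), the chemokine gene Ccl8 was at 19.9, 137 and 256 CPM, 12.9-fold higher in KO than in WT (8.64 to 20.1), but it was counted in 8 WT and 43 KO cells. The lectin receptor gene Clec12a was 7.16-fold higher (4.76 to 11.2), Hspa1b 5.26-fold (3.62 to 7.88) and Hspa1a 4.13-fold (3.16 to 5.49). The adhesion molecule gene Vcam1 was at 101, 166 and 9.74 CPM, 10.4-fold lower (6.57 to 17.1). Ccn1, a matrix-associated gene induced through YAP, was at 43.8, 31.2 and 0.885 CPM, with 2 counts in KO. Pomc and Gh, at 58346, 31745 and 13332 CPM, were also lower and stand here for free RNA, with Gh at 94501 CPM in WT and 26901 CPM in KO endothelial-like cells. The interferon response list was higher in 8 of 11 genes (median 0.31), with Isg15 at 39.0, 53.6 and 74.3 CPM and, on the other side, Ifi27 at 173, 118 and 92.0 CPM.

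In endothelial-like cells (207 in WT, 552 in KO), Igf1 was at 4.02, 27.9 and 109 CPM, with 3 counts in WT and 255 in KO, a ratio of 27.1 (9.16 to 132). The water channel gene Aqp1 was at 1.34, 16.4 and 55.0 CPM, with 1 count in WT, a ratio of 41.1 (7.25 to 1635). Gsta3, a glutathione transferase gene, was at 0 in WT and 37.1 CPM in KO, at least 9.24-fold higher with 3 counts as the floor, while the exact interval of the ratio starts at 7.35. Lyz2, a lysozyme gene of myeloid cells, was at 2.68, 13.1 and 45.2 CPM, counted in 6 KO cells. Ccn2, which encodes connective tissue growth factor, was at 319.9, 266 and 29.8 CPM, 10.7-fold lower in KO (8.18 to 14.2), and Mmrn1 7.33-fold lower (4.31 to 12.9). Nnat was 4.46-fold and Pomc 301-fold lower. The interferon response list was higher in 9 of 12 genes (median 0.50, 0.27 to 0.65), with Ifit1 at 16.1, 18.8 and 37.1 CPM, Rtp4 at a log2 ratio of 0.83 and Bst2 at 365, 371 and 595 CPM. Marker genes of other cells differed too: in these endothelial-like cells those of macrophages summed to 17.4, 75.4 and 94.2 CPM, against 21491, 22144 and 22403 CPM in macrophage-like cells, and those of mural cells to 83.0, 19.7 and 20.5 CPM. Those of red cells summed to 929, 14723 and 1579 CPM, highest in HT. Those of somatotropes summed to 94660.4, 39683 and 26962 CPM and those of lactotropes to 38117, 9726 and 24141 CPM, and the secretory granule list was lower in 10 of 11 genes (median -0.68). With the profiles of somatotrope-, lactotrope- and gonadotrope-like cells taken off in proportion to Gh, Prl and Cga, 34.6% of WT and 14.97% of KO counts, the interferon median was 0.19 (-0.040 to 0.34), so a difference beyond this free RNA was not detectable at this depth.

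Stem-cell-like cells (264 in WT, 358 in HT, 415 in KO) express Sox2, Sox9 and other genes of the pituitary's own stem cells. Isg15, an interferon-induced gene, was at 41.3, 79.1 and 119 CPM, 2.88-fold higher in KO than in WT (2.18 to 3.86). The interferon-induced GTPase gene Tgtp2 was 2.92-fold higher (2.14 to 4.06), Timp4, an inhibitor of matrix proteases, 2.60-fold (1.97 to 3.47), and the actin-binding genes Cnn2 and Tagln 4.61-fold (2.95 to 7.55) and 7.21-fold (3.51 to 17.2). Mgp was 5.16-fold higher (2.48 to 12.4). Timp4 and Tagln lay above their endothelial-like levels in WT and KO. Isg15, Tgtp2, Cnn2 and Mgp lay below theirs, which were 135 and 219, 167 and 260, 66.9 and 108, and 45.5 and 37.1 CPM. For these genes free RNA was not told apart from expression. Tagln and Mgp each had 8 WT counts, in 3 and 6 cells, and were counted in 24 and 21 KO cells, and marker genes of mural cells summed to 48.0, 52.0 and 78.9 CPM in this class. Several genes named by the rule rested on few cells: Bpifa1, a leading gene of this cluster, had 2257 KO counts in 1 cell, and Cxcl10, AW112010 and Klk1 were counted in 3, 4 and 6 KO cells. On the lower side Dusp6, a phosphatase induced by ERK signalling, was at 75.8, 82.0 and 29.2 CPM, 2.60-fold (1.91 to 3.55), and the aldehyde oxidase gene Aox1 2.45-fold (1.77 to 3.39). Sparcl1 was 4.25-fold, the lipoxygenase gene Alox15 3.76-fold, the sulfotransferase gene Sult1a1 3.75-fold, Ramp1 3.74-fold, the potassium channel gene Kcna5 3.15-fold and Prcd 2.33-fold lower. Pomc, at levels that free RNA could give, was 344-fold lower. The ribosomal protein list was higher in 78 of 86 genes (median 0.20). The Pit1 lineage list had a median of 0.47, with 3 of its 5 measured genes higher, but of 0.24 with at least 20 counts and 0 with no filter on counts. Prl was at 8765, 5034 and 12105 CPM and Gh, lower in KO, at 38926, 37134 and 21934 CPM, both below their levels in endothelial-like cells (38061, 9713 and 24120.2 CPM, and 94501, 39604 and 26901 CPM). Cga, at 4389, 4094 and 6523 CPM, was above its level there (1931, 1777 and 3507 CPM).

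Genes induced by glucocorticoids stood lower in KO in most classes. Fkbp5, a co-chaperone of the glucocorticoid receptor and a well known target of it (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), was at 38.2 CPM in WT, 36.4 in HT and 9.29 in KO macrophage-like cells. It was at 51.7, 60.1 and 18.5 CPM in somatotrope-like, 56.8, 68.3 and 35.7 CPM in stem-cell-like, and 24.9, 26.8 and 15.7 CPM in lactotrope-like cells. The list's median log2 ratio of KO over WT was -0.71 (-0.83 to -0.57) in macrophage-like cells with 11 of 12 genes lower, -0.43 (-0.82 to -0.34) in endothelial-like cells with 9 of 11 (-0.89 over genes with at least 20 counts), and -0.36 (-0.49 to -0.31) in stem-cell-like cells with 14 of 15. It was -0.22 (-0.30 to -0.16) in somatotrope-like cells with 11 of 15, but -0.12 in cluster 1 alone, -0.37 with median-of-ratios or TMM factors, -0.46 without hormone and mitochondrial genes in the totals and -0.33 with a pseudocount of 1 CPM. It was -0.15 (-0.27 to -0.11) in gonadotrope-like cells with 10 of 14, but -0.10 with median-of-ratios and -0.085 with TMM factors. In lactotrope-like cells it was -0.23 (-0.28 to -0.18) with 12 of 15 genes lower, but 0.015 with the authors' scaled counts, -0.12 with median-of-ratios or TMM factors, -0.13 without hormone and mitochondrial genes in the totals, -0.34 with that pseudocount, -0.13 in cluster 0 alone and -0.0042 in cluster 4 alone. Against HT the medians were -0.60, -0.44, -0.66, -0.49, 0.03 and -0.26 in macrophage-, endothelial-, stem-cell-, somatotrope-, gonadotrope- and lactotrope-like cells. Against HT the gonadotrope-like median lay at percentile 50.9 of the random lists, so it did not meet the rule for a list to be described. HT over WT the medians were -0.04, -0.32, 0.09, 0.16, -0.12 and 0.01 in the same order. Cdkn1a, the cell cycle inhibitor p21, Gadd45g and the transcription factor Klf9 were lower in KO than in WT in 6 of 6 classes, and Fkbp5 and Ddit4, an inhibitor of mTOR signalling, in 5 of the 5 classes where they were measured. For Gadd45g the macrophage-like ratio was 0.983 (0.837 to 1.16), within counting error of no difference. The metallothionein genes Mt1 and Mt2, Cebpd and Errfi1 were lower in 5 of 6, Tsc22d3 in 4 of 6 and Dusp1 in 1 of 6. Among genes measured in fewer classes, Sgk1 was lower in 4 of 5, Per1 in 3 of 5, Zbtb16 in 3 of 3, Pdk4 in 2 of 3 and Lcn2 in 2 of 2.

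**Figure D3:**
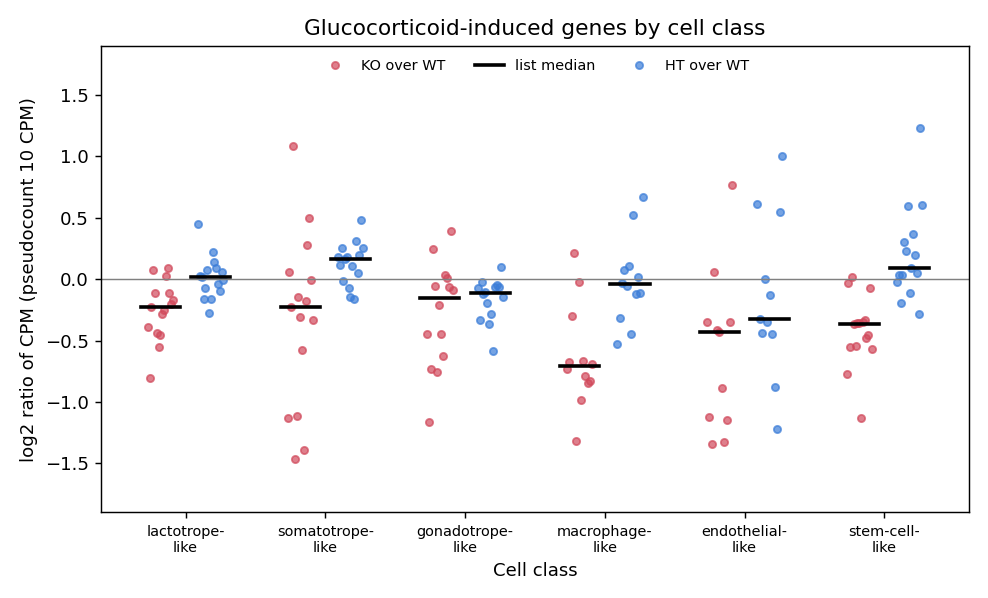
Log2 ratios of KO over WT and of HT over WT for the genes of the glucocorticoid-induced list (points) and their medians (bars) in each of 6 cell classes, 1 library per genotype. The KO over WT medians ran from -0.71 in macrophage-like to -0.15 in gonadotrope-like cells, and with the authors' scaled counts the lactotrope-like median of -0.23 became 0.015.

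Since the series concerns signals between lineages, ligands and receptors were compared by class. Igf1 was higher in KO than in WT in endothelial-like and somatotrope-like cells, and also in macrophage-like cells, at 24.7, 21.3 and 50.4 CPM, 2.05-fold (1.36 to 3.15). In somatotrope-like cells Igf1 lay below its endothelial-like levels (4.02, 27.9 and 109 CPM). Macrophage-like cells had Igf1 above that level in WT and below it in HT and KO. Free RNA was not told apart from expression in either class. Over all cells Vegfa, the main vascular growth factor, was 3.01-fold higher (2.81 to 3.22) and the FGF receptor gene Fgfr1 was at 4.72, 5.79 and 18.2 CPM. Within gonadotrope-like cells Fgfr1 was at 34.0, 34.8 and 67.2 CPM, 1.98-fold higher (1.69 to 2.33). Inhbb, a subunit of activin B and inhibin B, was at 83.1, 59.4 and 26.2 CPM in gonadotrope-like cells, 3.17-fold lower (2.79 to 3.61). Dlk1, a non-canonical Notch ligand, was at 1001, 987 and 494 CPM in lactotrope-like cells, 2.03-fold lower (2.00 to 2.06). Lamc1, a laminin chain of basement membranes, was 3.50-fold higher in endothelial-like cells (2.51 to 5.02). Id1, a target of BMP signalling, was at 161, 179 and 84.6 CPM in stem-cell-like cells, 1.903-fold lower (1.57 to 2.30). These genes were picked from the fixed lists after their values were seen, and levels of a ligand or a receptor do not measure signalling.

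Few cells were dividing in any library. The proliferation gene Mki67 was counted in 42 WT cells (0.374%, 0.270 to 0.506), 37 HT cells (0.288%, 0.203 to 0.397) and 39 KO cells (0.291%, 0.207 to 0.397). The KO over WT ratio of this share was 0.777 (0.489 to 1.23), a difference not detectable at this depth. Top2a, a topoisomerase of dividing cells, was counted in 39, 24 and 39 cells. Cluster 16, led by immunoglobulin genes, held 8 of the 39 KO cells with Mki67 and 10 of the 39 with Top2a. In WT it held 1 of 42 and 2 of 39, so the totals over all cells came in part from that cluster. Other measures stood lower in KO than in WT. The cycling cluster 20 held 9, 2 and 2 cells, a KO over WT ratio of shares of 0.186 (0.0195 to 0.898). Over all cells 13 of 15 measured genes of the G2M list were lower in KO than in WT (median -0.058, percentile 0), and 5 of 15 were lower than in HT (median 0.016). In somatotrope-like cells Mki67 was counted in 13 WT (0.347%), 14 HT (0.365%) and 4 KO cells (0.109%), and Top2a in 4, 5 and 5. In stem-cell-like cells Mki67 was counted in 1 of 264 WT, 0 of 358 HT and 1 of 415 KO cells. Top2a was counted there in 3, 2 and 1 cells, and the summed G2M list was at 99.4, 5.41 and 17.7 CPM. Both were highest in WT, on few cells.

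HT against WT compared libraries that both held Pomc cells. Over all cells the heat shock genes Hspa1a (75.2 and 158 CPM) and Hspa1b (51.4 and 100.5 CPM) were 2.11-fold (2.05 to 2.16) and 1.96-fold (1.897 to 2.02) higher in HT. Rbm3 was 2.13-fold higher (2.07 to 2.20), the centrosomal gene Sfi1 2.30-fold (2.18 to 2.41) and Fshb 1.81-fold (1.79 to 1.83), beside a gonadotrope-like share 1.23-fold higher (1.08 to 1.39). On the lower side the immunoglobulin genes Igha, Igkc and Iglc1 and the joining chain gene Jchain were 8.93-fold, 5.41-fold, 217-fold and 6.14-fold lower, beside cluster 16, which those genes led and which held 72 cells in WT and 17 in HT. Tshb, the beta subunit of thyroid-stimulating hormone, was at 685 and 259 CPM, 2.65-fold lower (2.61 to 2.68), beside a thyrotrope-like share of 0.811% in WT and 0.405% in HT. In KO Tshb was at 833 CPM.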

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

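No test was chosen for this part, and the value below is given without an explanation. A row that the authors named LacZn, which the comparisons above do not use, held 5 counts in the HT library (1 in cluster 6 and 4 in cluster 7) and 3 counts in the KO library (all in cluster 11), against 0 counts in the WT library, where a count of 0 allows up to 0.0280 CPM.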

How the results depend on the processing

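Chosen after the data were seen were the shares outside clusters 6 and 7, cluster 12 counted as lactotrope-like, the authors' scaled counts, totals without nuclear mitochondrial copies, single clusters, shares of cells with a count, and other measures of dividing cells. Of 228 recomputed list medians, 139 stayed within their counting interval, 86 moved with the same sign and 3 reversed. Of 492 recomputed ratios of named genes, 318 stayed, 172 moved and 2 reversed. The glucocorticoid-induced medians of macrophage-like and stem-cell-like cells stayed within their intervals under every alternative run. A base meant to hold hormone-producing and stem cells left out only macrophage-, endothelial-, fibroblast- and pituicyte-like cells and cluster 16. It thus kept the unnamed clusters 11, 12, 13 and 17 and the cycling cluster 20. On that base the KO over WT ratio of shares was 1.04 for lactotrope-like and 0.860 for somatotrope-like cells. Outside clusters 6 and 7 it was 0.828 for lactotrope-like, 0.686 for somatotrope-like, 2.60 for gonadotrope-like, 1.87 for endothelial-like and 1.10 for stem-cell-like cells, and it reversed to 0.977 for macrophage-like cells, since the smaller base raises WT shares. With cluster 12 the lactotrope-like ratio was 1.05. By share of cells with a count, Tbx19 was 16.8-fold lower in KO. Pomc was lower by 398-fold with median-of-ratios factors, 391-fold with TMM, 394-fold without hormone and mitochondrial genes in the totals and 415-fold with the authors' scaled counts. The glucocorticoid-induced median over all cells was -0.49, -0.47 and -0.51 under the first 3 of these and -0.53 with a pseudocount of 1 CPM. In lactotrope-like cells it was -0.12, -0.12, -0.13 and -0.34 in that order, -0.13 in cluster 0, -0.0042 in cluster 4, and reversed to 0.015 with the authors' scaled counts. In somatotrope-like cells it was -0.37, -0.37, -0.46 and -0.33, and -0.12 in cluster 1. In gonadotrope-like cells it was -0.10 with median-of-ratios factors and -0.085 with TMM, and in endothelial-like cells -0.89 with at least 20 counts. The authors' scaled counts, which give every cluster its own factor and so change its weight, reversed the all-cell values of the gonadotrope list (-0.012), Lhb (-0.012) and AC151602.1 (-0.012), and the stem cell list of somatotrope-like cells reversed to 0.0037 with no filter on counts. Apart from the changes of base and of cluster weight, the cause was not tested. A minimum of 30 cells would have compared 13 classes in place of 6. Not run, because the tables used give sums per cluster, were the mean of each cell's CPM, thinning of cells to equal depth, a minimum of counts per cell, Scrublet, reassignment of cells by marker scores, thresholds of 1, 2 or 3 G2M genes or of 2 counts per cell. No replicate could be left out, with 1 library per genotype. In simulated data with Poisson error only, the naming rule recovered 23% (stem-cell-like) and 1% (all cells) of 2-fold differences, and 88% and 96% of 4-fold ones. The cutoff itself, and not depth alone, thus leaves most 2-fold differences unnamed.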

Other observations

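Of the tests in this part, those of free RNA of Pomc cells and of a shift of the whole library were set out before their result was seen, and all others, with the interval of the latter, were chosen after the result was seen.

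Cluster 11 held 53 cells in WT, 107 in HT and 871 in KO. Its KO cells had the cell cycle inhibitor gene Cdkn1c at 609.9 CPM. Pax7, the factor that specifies melanotropes (chromosome 4, 139737062 to 139833528), was at 37.7 CPM (33.1 to 42.8), in 124 of 871 KO cells, or 14.2% (11.98 to 16.7), against 0 of 53 WT and 0 of 107 HT cells. Pcsk2, the convertase that melanotropes use to process the Pomc precursor, was at 39.7 CPM in WT, 8.60 in HT and 336 in KO, and Oacyl at 0, 1.23 and 24.0 CPM. The corticotrope receptor genes Crhr1 and Avpr1b were at 0.316 and 0 CPM in KO cluster 11, against 21.4 and 15.3 CPM in WT. Those WT values rest on 53 cells with 327202 counts of all genes, so on few counts. Free RNA of clusters 6 and 7, which the KO library lacked, was not told apart from expression. LacZp was counted in 65 of the KO cells of cluster 11.

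Among smaller classes, the glucocorticoid-induced list had a median log2 ratio of KO over WT of -0.62 in fibroblast-like cells (6 of 8 genes lower), -0.48 in thyrotrope-like cells (6 of 7), -0.55 in cluster 11 (11 of 13), -0.44 in cluster 17 (3 of 5), -0.18 in cluster 13 (8 of 8), -0.10 in cluster 12 (5 of 8) and 0.04 in cluster 16 (3 of 6). The make-up of cluster 11 differed between libraries, as given above, so its value does not compare like cells. Under the rule for named genes, 0 genes stood in opposite directions in any pair of the 6 classes compared. Few genes met the rule in some classes, with Eno3 alone named as higher in lactotrope-like cells. Genes that did not meet it could differ in direction: Tsc22d3 ran from -0.69 to 0.77 across classes.

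The first pattern weighed was the glucocorticoid-induced list, whose median was lower in KO than in WT in 6 classes, though not lower than in HT in gonadotrope-like cells. Free RNA of Pomc cells was argued against, since taking the Pomc-cell profile off the WT library left at least 90.7% of the median in each class, and so was that of somatotropes, lactotropes and gonadotropes, since taking off their profiles in each library in proportion to Gh, Prl and Cga left at least 92.0%. In endothelial-like cells the latter removal moved the median from -0.43 to -0.72 (-0.998 to -0.573). A weaker response to dissociation was argued against in somatotrope-like cells, where the median of the immediate early and heat shock list was 0.38 over WT (0.075 to 0.53 with its members redrawn), 0.46 over HT (0.38 to 0.61) and 0.099 to 0.39 over WT under the alternatives run. It stayed open in the other 5 classes, where these intervals held 0 against WT or HT, and the median farthest from 0, 0.30 in endothelial-like cells, was 0.059 over HT (-0.083 to 0.25). In macrophage-like cells the median over WT was -0.060, at percentile 1.7 over WT and 2.5 over HT. There the 6 genes higher than in WT were Fosb and the heat shock genes, and the other immediate early genes were lower. A difference between libraries other than genotype cannot be told apart from genotype with 1 library each, HT over WT reaching -0.32 in endothelial-like cells. A candidate explanation, held as a hypothesis, is lower circulating glucocorticoid in mice whose pituitaries held little Pomc transcript. It was not tested, because neither ACTH nor any other hormone was measured.

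The second pattern was the higher share of gonadotrope-like cells in KO. Loss of the Pomc clusters from the base was argued against as the whole cause by the ratio of 2.60 (2.34 to 2.89) outside those clusters. The hypothesis that cells of the Pomc lineage had taken a gonadotrope-like state was tested through LacZp: had the 1125 extra cells carried it at the rate of KO cluster 11, 7.46%, 84.0 cells would have shown it, and 1 did, with an upper limit of 5.57. That argues against cells transcribing the row at that rate, while cells that had silenced it stay open. Dissection or recovery that differed between libraries also stays open, since the pituicyte-like share was 9.95-fold higher in KO (5.05 to 22.3), and genotype itself may act through division or survival, which was not tested.

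The third pattern was the place of KO somatotrope-like cells in cluster 5 and not cluster 2. Depth of the cells was argued against: cluster 2 cells had 1.22-fold more counts in HT than in WT and shared the cluster, whereas KO cells of cluster 5 had 0.905 times the counts of WT cells of cluster 2. A shift of the whole KO library was weighed on 60 genes apart between these clusters, which kept 21.8% (21.1 to 27.2) of their median difference in lactotrope-like cells, with 24 of 30 measured genes in the same direction, and 10.5% (4.36 to 14.7) in gonadotrope-like cells, with 20 of 32. Other classes were not run. The lactotrope-like interval held the limit set in advance, so a partial shift of the library stays open beside a response of somatotropes to genotype, which was not tested further.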
